A study of Mus musculus with 16 samples.

How the data were processed

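The series holds CITE-seq data, in which messenger RNA and antibody-linked oligonucleotide tags are counted in the same single cells. Per the labels, NK cells were sorted from the spleens of 8-week-old mice, either with a floxed Reg-1 gene (labelled WT) or with Reg-1 deleted in NK cells (labelled KO). Reg-1 is Regnase-1, an RNA-degrading enzyme encoded by Zc3h12a. The labels list 16 samples in 2 groups: RNA and antibody libraries of each genotype, each with 4 L numbers. Per the labels' protocol, cells were stained with oligonucleotide-tagged antibodies, captured with 10x Genomics 5' chemistry and sequenced on an Illumina NovaSeq instrument.

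The deposited values were raw counts: each entry was the number of unique molecular identifiers (UMIs) of 1 feature in 1 barcode, with no normalization. Cell Ranger 6.0.0, Seurat and the mouse build mm10 were named in the submitters' processing notes, without the step each was used for. Per the file headers, the matrices held whole numbers for 31053 genes and 6 antibody tags (NK1.1, CD11B, CD27, IGG2A, CD49B and NKP46), and the file names describe the barcodes as filtered. There were 2 matrices, 1 per genotype. Their barcodes carried no mark of the L number, so the 4 L numbers of a genotype were pooled and each matrix counted as 1 sample. Whether the L numbers were lanes or separate libraries was not given. The number of mice behind each matrix was not given in the sources used here.

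With 1 sample per group there was no replicate check. The comparisons between the libraries, the cell type markers, the rule for naming genes, the gene lists and all alternatives but 8 were fixed before the data were examined, and the tests of explanations were not. No test between the genotypes was run, and no p-value is given. Each count carries an exact Poisson interval and each share of cells an exact Clopper-Pearson interval, both at the 95% level and both covering counting error only. A count of 0 was set to 3 counts where a bound was needed. For ratios within subsets of cells the interval was derived from the exact binomial interval of the split of the counts.

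The matrix labelled WT held 11955 barcodes and 49591798 gene UMIs, and the matrix labelled KO 8159 barcodes and 39094818 gene UMIs. Cells with 500 or more genes and 10% or less mitochondrial counts were kept, which left 11815 and 7974 cells and removed 140 and 185 barcodes. Median UMIs per kept cell were 3533 and 4150. Doublets were called per matrix with Scrublet in scanpy 1.11.5 at an expected rate of 6%. The caller marked 0 and 3 cells, so it has not worked on these matrices, and cells with more than 2 times their matrix's median UMIs (1094 and 820 kept cells) were left out as an alternative.

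Cells of both matrices were clustered together with scanpy 1.11.5 and igraph 0.11.9 (2000 variable genes, 30 principal components, 15 nearest neighbours, Leiden resolution 0.5, seed 0). No batch integration was applied. Clusters were called "X-like" from fixed cell type markers, 13 of them for NK cells. A cluster whose leading genes went against a name stayed unnamed. NK-like cells numbered 8687 in the library labelled WT and 5287 in the library labelled KO, with median UMIs of 3308 and 4103. NK-like cells were then subclustered without the 940 genes that differed 1.5-fold or more between the matrices, so that subcluster sizes could be set side by side.

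Gene counts were summed over the NK-like cells of each matrix, to totals of 33572422 and 25054947 UMIs, and divided by these totals to give CPM. The log2 ratio is KO over WT. Genes were counted by size: CPM of 20 or more in the higher matrix and a ratio of 2-fold or more. Named genes followed a fixed rule. Zc3h12a came first, then Ifng, Pou2f2 and Pou2af1. Then came the 12 genes with the highest and the 12 with the lowest ratio among those counted, provided that all subclusters with 200 or more cells in each matrix had the same direction. Immunoglobulin and T cell receptor segments, haemoglobin, mitochondrial and Y-linked genes, Xist, Tsix and predicted genes were left out of this ranking, which removed 5 genes. Of each fixed list, the 2 to 4 members with the largest absolute ratio at CPM of 20 or more could be named, and all 6 antibody tags were reported. The 13 genes whose share of cells with a UMI is given were fixed as well. Outside this rule, Il6, Inpp4b, Itga1, Cxcr6, Ccr7, Egr1 and Nr4a1 were chosen after their values were seen. So were the genes that describe clusters and subclusters, the neighbours that overlap a named gene and the T cell receptor segments. The transcripts of the tags were added. Some genes that met the rule were not used here.

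The fixed gene lists numbered 24. Of their 392 symbols, 390 matched the deposited symbols and 2 matched through gene IDs. A list's value is the median log2 ratio of its members with mean CPM of 5 or more. Its percentile is taken among 10000 random lists of the same size matched on mean expression in 20 bins, and describes these 2 libraries only. Antibody tags were given per cell as a centred log ratio (log2) over the 6 tags. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs. Coordinates are those of GRCm38, the assembly that mm10 names, from the RefSeq annotation, matched by gene symbol or ID.

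The counting step and the list step were checked on simulated counts for 5647 genes. These were Poisson draws from the rates of the library labelled WT, with the totals of the 2 libraries. They held no variation between cells, mice or libraries beyond counting. The check therefore covers the arithmetic and gives no error rate for the genes and lists reported below. Of 200 genes given a known fold, all 34 at 3-fold higher, 34 at 6-fold higher, 34 at 3-fold lower and 30 at 6-fold lower were counted at 2-fold. None of the 34 genes at 1.5-fold higher or the 34 at 1.5-fold lower was counted, and 0 genes with no simulated difference were. Intervals held the simulated fold for 94.1% to 100% of the genes. Of 20 simulated lists of 20 genes with no shift, 18 lay between the 2.5th and 97.5th percentile, and 20 of 20 lists shifted 1.5-fold lay above it.

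Alternatives covered the scaling (edgeR 4.0.16 TMM factors in R 4.3.3, and a DESeq2-style median of ratios), thinning, the mean over cells, equal subcluster weights, stricter cell filters, all kept cells, other totals, other CPM minimums and folds, list summaries, tag scales, and clustering resolution and seed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Fits by L number were left out because cells could not be assigned to L numbers. Reads, and any per-mouse assignment of cells, were not analysed here.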

Results

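Splenic NK cells of mice labelled as lacking Regnase-1 in NK cells were compared with those of floxed control mice by counting transcripts and 6 surface antibody tags in single cells. Regnase-1, encoded by Zc3h12a, is an RNase that degrades messenger RNAs of inflammatory proteins, among them Il6. The cells of each genotype were deposited pooled in 1 matrix, called a library below. Whether its 4 L numbers were lanes or separate libraries was not given, and cells could not be assigned to them, so the values below compare 1 pool with another and carry counting error only. The NK-like cells numbered 8687 in the library labelled WT and 5287 in the library labelled KO, and they yielded 33572422 and 25054947 gene UMIs. Median depth was 3308 and 4103 UMIs per NK-like cell. In all, 5770 genes reached 20 CPM in at least 1 of the 2 libraries.

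To determine how the targeted gene itself differed, Zc3h12a was read first. Zc3h12a (chromosome 4, 125118414 to 125127881 in GRCm38) encodes an RNase that has been reported to destabilize its own transcript. Its level was higher in the library labelled KO, at 198 CPM (192 to 203), than in the library labelled WT, at 32.0 CPM (30.1 to 33.9), a log2 ratio of 2.63. The counts were 4955 and 1073. All 4 NK-like subclusters compared gave the same direction, with ratios of 2.681, 2.497, 2.484 and 3.160 in subclusters 0, 2, 3 and 4. Tags from the 5' end lie near the transcription start, and the deleted exons were not given, so the level of Zc3h12a does not check the deletion. The genotypes are therefore given by their labels throughout.

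To determine which genes differed most, NK-like cells of the 2 libraries were compared gene by gene. The named genes with the highest ratios have varied roles. Irak3 encodes a brake on Toll-like and IL-1 receptor signalling, Pou2f2 encodes the transcription factor Oct2, Cd79b encodes a signalling chain of the B cell receptor, and Tnfrsf13b encodes TACI, a receptor for BAFF and APRIL. Among 5770 genes, 94 differed 2-fold or more, 61 higher and 33 lower in the library labelled KO, and 21 were 4-fold or more higher against 1 lower. Of the 94 genes, 76 had one direction in all 4 subclusters compared (53 higher, 23 lower). A gene with 3 or fewer counts in both libraries of a subcluster got no ratio there. Such genes, among them Cx3cr1 in subcluster 4, were not counted among the 76. The median log2 ratio of all genes was -0.12, and it was -0.01 after scaling by either TMM or the median of ratios. Under these scalings 92 genes differed 2-fold or more, of which 76.1% were higher in the library labelled KO, against 64.9% with plain totals.

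Among genes that met the naming rule, Irak3 (chromosome 10, 120141648 to 120202130) had the highest ratio, from 0.238 CPM (0.103 to 0.470) in the library labelled WT to 42.0 CPM (39.5 to 44.6) in the library labelled KO, a log2 ratio of 7.46. Ctsh, a lysosomal cysteine protease gene (chromosome 9, 90054267 to 90076095), had 0.387 and 25.9 CPM (6.06), and Pik3r6, for a regulatory subunit of PI3-kinase gamma, had 0.715 and 23.2 CPM (5.02). Pik3r6 had 1.59 in subcluster 4. Over all kept cells, dendritic-like cells included, the ratio of Ctsh was 0.72, that of Irak3 5.75 and that of Pik3r6 4.33. Tnfrsf13b (chromosome 11, 61126283 to 61153170) had 4.23 CPM (3.56 to 4.99) and 54.4 CPM (51.6 to 57.4), a log2 ratio of 3.69. Its neighbour Usp22, which overlaps it, had a ratio of -0.17. Cd79b (chromosome 11, 106311341 to 106314562) had 2.83 CPM (2.29 to 3.46) and 31.1 CPM (29.0 to 33.4), a log2 ratio of 3.46. Pou2f2 (chromosome 7, 25087350 to 25180797) had 23.3 CPM (21.7 to 25.0) and 247 CPM (241 to 254), a log2 ratio of 3.41, while the overlapping D930028M14Rik had 0.02. Over all kept cells Tnfrsf13b had 2.85 and Cd79b 2.29, and in subcluster 4 Cd79b had 1.90. Pou2af1, the gene of the Oct2 coactivator, was nearly absent, at 0.0894 CPM (0.0184 to 0.261) and 0.519 CPM (0.276 to 0.887) from 3 and 13 counts.

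The annexin gene Anxa8 had 5.004 and 57.03 CPM (3.51, but 0.59 in subcluster 4), Tmem154 had 7.36 and 81.7 CPM (3.47, and 2.48 over all kept cells), the adhesion gene Amigo1 had 4.08 and 36.1 CPM (3.14), and the carboxylesterase gene Ces2c had 3.72 and 30.2 CPM (3.02). The cytokinesis gene Prc1 had 2.62 and 25.1 CPM (3.26, but 1.73 in subcluster 0 and 2.46 over all kept cells), whereas Rccd1, which overlaps it, had -0.49. Mab21l2 had 0.149 and 22.9 CPM (7.26), and Lrba, within which it lies, had a ratio of 0.40. Ifng (chromosome 10, 118441046 to 118445894), the main cytokine of NK cells, had 145 CPM (141 to 149) and 272 CPM (265 to 278), a log2 ratio of 0.91. Il6 was picked after its values were seen. It had 0 counts in the library labelled WT and 444 in the library labelled KO, 17.7 CPM (16.1 to 19.4), at least 198-fold higher against a limit of 3 counts over the library, and no cell held more than 0.676% of them.

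Genes lower in the library labelled KO included a chemokine receptor, an ephrin and a potassium channel. Ccr2 (chromosome 9, 124101918 to 124109140) encodes the receptor for CCL2 that guides leukocytes out of bone marrow. It was the most abundant of the named genes with the lowest ratios. Ccr2 had 343 CPM (337 to 349) in the library labelled WT and 109 CPM (105 to 113) in the library labelled KO, a log2 ratio of -1.66. Cdk5rap1 (chromosome 2, 154222011 to 154373038), for a transfer RNA modifying enzyme, had the lowest ratio of the named genes, with 29.5 CPM (27.7 to 31.4) and 4.91 CPM (4.08 to 5.86), a log2 ratio of -2.59. The calmodulin-binding gene Nrgn had 45.8 and 12.8 CPM (-1.84), Cpne7 had 27.7 and 9.02 CPM (-1.62), and the potassium channel gene Kcnj8 had 74.7 and 25.1 CPM (-1.57, with -3.08, -1.46, -2.28 and -2.58 in subclusters 0, 2, 3 and 4). The orphan receptor gene Gpr25 and the ephrin gene Efnb1 had ratios of -1.37 each (Gpr25 -0.25 in subcluster 4), Camk2b had -1.28, and Lyst, the lysosomal trafficking gene mutated in beige mice, had -1.25. AC163354.1 had 41.1 and 14.6 CPM (-1.49, from -0.78 in subcluster 0 to -3.04 in subcluster 4). Ugt1a7c had 43.7 and 11.3 CPM (-1.95). Ugt1a9 and Ugt1a6a, which overlap it, had 0.387 and 0.536 CPM in the library labelled WT. Ugt1a genes share their last exons, whereas 5' tags lie near the transcription start. Whether another member adds to these counts was not tested.

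**Figure D1:**
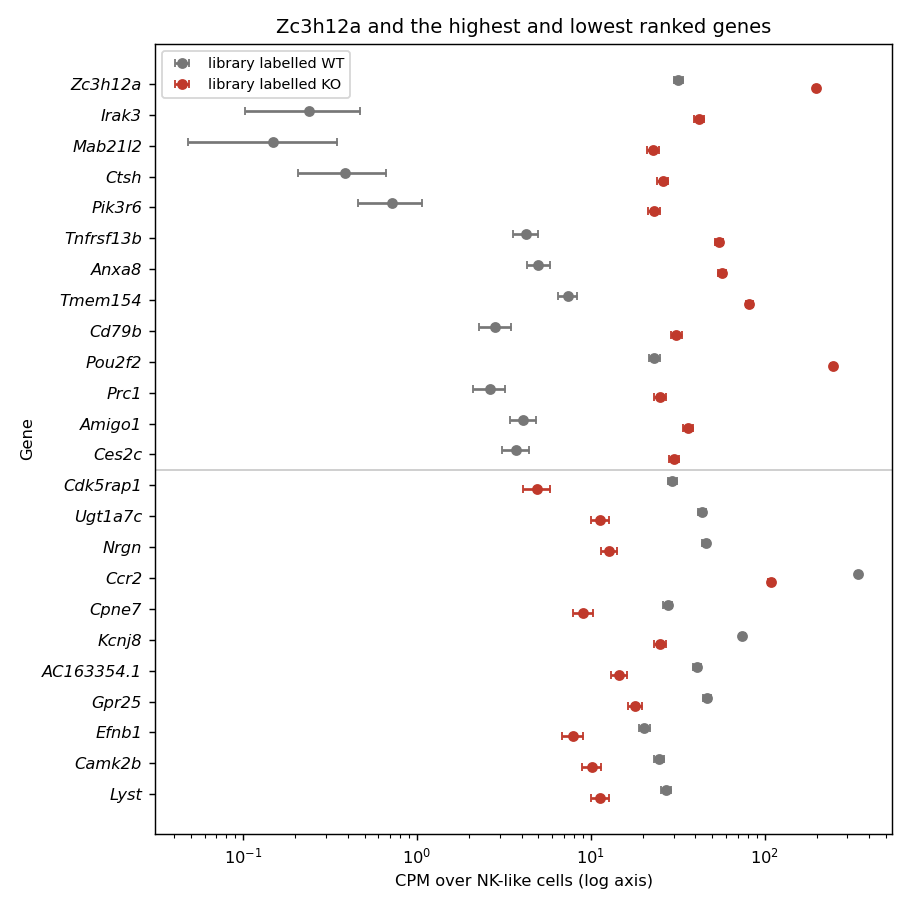
Levels of Zc3h12a and of the named genes with the highest and the lowest ratios in NK-like cells (grey, library labelled WT; red, library labelled KO), with counting intervals. Irak3 had 0.238 and 42.0 CPM, and Ccr2 had 343 and 109 CPM.

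To determine whether transcripts that Regnase-1 is known to degrade were higher in the library labelled KO, a list of published targets was compared with random lists of like expression. Icos encodes a costimulatory receptor, Batf encodes an AP-1 family transcription factor, and Nfkbiz encodes a nuclear regulator of NF-kB target genes. The 8 measured targets had a median log2 ratio of 0.67, at the 100th percentile of random lists (central 95%, -0.28 to 0.04), with 5 higher and 3 lower and Il6 taken at its bound. Icos had 1.77 (1.05 over all kept cells), Batf 1.64 (0.74 in subcluster 2) and Nfkbiz 1.13, whereas Nfkbid had -0.22. The median was 0.20 or more under all alternatives. The mean of the members was 1.48 with Il6 at its bound, and without Il6 the mean was 0.61 and the median 0.20, at the 99.9th percentile. Of the fixed list for Oct2 and its coactivator, Pou2f2 was the 1 member with 5 CPM, so no percentile was computed for it.

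Genes of the NF-kB pathway, whose members include the subunits Nfkb1 and Relb and their inhibitors, lay lower in the library labelled KO. Their median log2 ratio was -0.34 (0th percentile), with 4 higher and 15 lower. Of the members at 20 CPM or more, Nfkbie (-0.99), Nfkb1 (-0.74) and Relb (-0.69) were lowest, whereas Nfkbiz had 1.13. Genes that tissue dissociation induces had a median of -0.31 (0th percentile), with Jun at -0.96 (-0.12 in subcluster 4), Ier2 at -0.67, Fosb at -0.66 and Junb at -0.65. Of the dissociation genes 2 were higher and 12 lower, with Egr1 at 0.17, and the immediate early gene Nr4a1 had 0.75. Handling of tissue induces genes of both lists, and whether it set these ratios was not tested. Genes of RNA decay regulators had a median of -0.12 (38.1st percentile), although Zfp36, itself an immediate early gene, had -0.66, and Zfp36l2 (0.072 in subcluster 4) and Arid5a had -0.36 each. Responses to type I interferon had a median of -0.11 (62.9th percentile), with Irf7 at -0.84 and Isg15 at -0.45, and took either sign over the alternatives. Genes that respond to interferon gamma had a median of 0.08 (99.8th percentile), with 11 higher and 7 lower, among them Socs3 (0.57), Tap1 (0.49), Psmb9 (0.48) and Socs1 (-0.50).

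To determine whether NK cell maturation genes differed, lists for immature and mature NK cells were compared. Immature NK cells express Cxcr3, Il7r and Thy1, and mature cells gain Cx3cr1 and Klrg1. The immature list had a median log2 ratio of -0.49 (0th percentile), with 1 higher and 12 lower: Cxcr3 had -0.97, Il7r -0.95 (from -2.65 in subcluster 2 to -0.65 in subcluster 4, and -0.41 over all kept cells), Thy1 -0.76 (-0.016 in subcluster 2 and -1.63 in subcluster 4) and Xcl1 -0.71. The mature list had a median of 0.23 (100th percentile), with 12 higher and 3 lower: Cx3cr1 had 1.32, Klrg1 1.18 and Gzmb 0.47, whereas Spn had -0.46. Both lists kept their sign in all alternatives. Residency and ILC1 genes had a median of 0.18 (99.5th percentile), with 5 higher and 3 lower. Cxcr6 had 2.83, Itga1 2.26, Inpp4b 1.74 and Rgs1 0.31 (-0.53 in subcluster 4), whereas Il7r had -0.95 and Rgs2 -0.33. Trafficking genes had a median of -0.16 (3.92nd percentile), with 6 higher and 12 lower. Their ratios ran from -1.66 for Ccr2 and -0.97 for Cxcr3 to 1.32 for Cx3cr1, 2.03 for Ccr7 and 2.83 for Cxcr6. The residency median took either sign over the alternatives, and the trafficking list did so as a mean (0.08).

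Receptors that NK cells use to sense target cells and cytokines were compared in 4 lists. Activating receptors, which trigger killing, had a median of -0.29 (0th percentile), with 5 higher and 15 lower: Ncr1, for NKp46, had -0.77, Crtam and Cd2 -0.63 each, and Slamf6 0.64 (-0.29 in subcluster 3). Inhibitory receptors had a median of -0.20 (1.16th percentile), with 3 higher and 11 lower. Among them Klra9 had -0.95, Klrc1 -0.50 and Klra3 -0.48, whereas Klrg1 had 1.18. Klra genes have near-identical copies, so the single Klra values are uncertain. Cytokine receptors had a median of -0.20 (2.91st percentile), with 2 higher and 15 lower, and included Il18r1 (-1.21, but 0.0017 in subcluster 4), Il2rb (-0.49) and Ifnar1 (-0.43). Costimulatory and TNF receptor family genes had a median of -0.36 (0.095th percentile), but took either sign over the alternatives: Tnfsf8 had 1.69 (0.73 in subcluster 4) and Cd28 -1.07, beside Tnfrsf13b and Icos.

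Effector genes encode the granzymes, cytokines and chemokines by which NK cells act. Cytotoxic granule genes had a median log2 ratio of 0.06 (95.5th percentile). Gzmk had 15.1 and 113 CPM (2.90), with 0.57, 4.65, 2.22 and 2.24 in subclusters 0, 2, 3 and 4 and 1.03 over all kept cells, and Serpinb6b had 0.55, Gzmm 0.53 and Gzmb 0.47. Gzmk, Gzmm and Gzmb lie on chromosomes 13, 10 and 14. Whether related granzyme genes add to their single values was not tested. Cytokine and chemokine genes had a median of 0.05 (94.3rd percentile), with Tnfsf14 at -1.21 and Ltb at -0.49 (from -1.69 in subcluster 2 to -0.10 in subcluster 4) against Ifng. Both medians took either sign over the alternatives.

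Transcription factors of lymphocytes had a median of -0.04 (92.9th percentile), of no stable sign. Ikzf2, the gene of Helios, had 2.42 (1.44 over all kept cells), whereas Id3, an inhibitor of E proteins, had -1.76 and Batf3 -1.63. The Id3 ratio came from part of the cells, with -0.032 and 0.72 in subclusters 0 and 2 but -2.71 and -2.55 in subclusters 3 and 4, and Batf3 had 0.067 in subcluster 0. Over all kept cells Id3 had -0.47 and Batf3 -0.51. Survival and apoptosis genes had a median of 0.07 (99.7th percentile), with Bcl2l1 at 0.33 and Bbc3 at -0.42 (0.499 in subcluster 4). Cytosolic ribosome genes had a median of 0.16 (99.8th percentile), with all 22 higher, led by Rplp0 (0.41) and Rpl10 (0.36). Iron genes had a median of -0.15 (25.0th percentile), with Slc11a2 at -0.76 and Fth1 at -0.38. Cell cycle genes had a median of -0.15 (32.9th percentile), with Mcm7 at -0.60 and Mcm5 and Mcm2 at -0.56 each, but 1.28 over all kept cells, where cycling cells were counted. Glycolysis genes had a median of -0.06 (62.7th percentile), with Pfkl at -0.53, Slc2a1 at -0.40 (0.14 in subcluster 4) and Gapdh at 0.27, and oxidative phosphorylation genes had -0.01 (70.4th percentile), with Uqcrh at 0.22 and Ndufa4 at -0.18. These last 2 medians took either sign over the alternatives. Of the 23 lists with 2 or more members, 6 lay below and 6 above the central 95% of random lists.

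**Figure D2:**
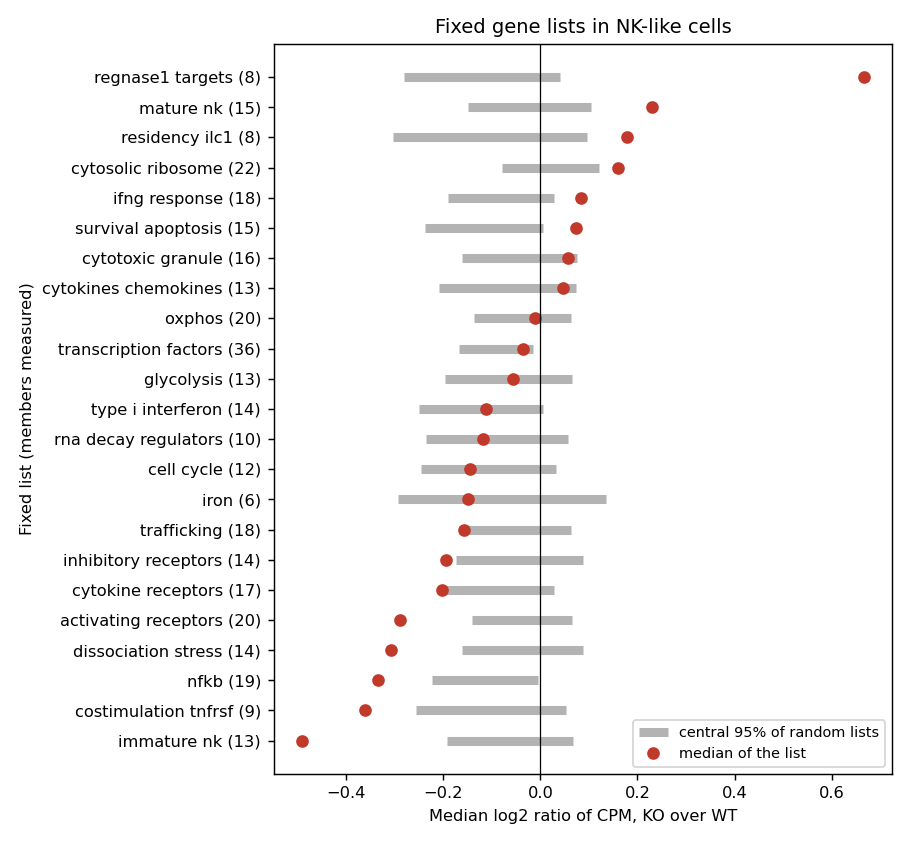
Median log2 ratio of each fixed list in NK-like cells (red), over the central 95% of random lists of like expression (grey). Regnase-1 targets had 0.67 and immature NK genes -0.49.

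To determine whether these ratios held within subsets of NK cells and in cells that are not NK cells, the 2-fold genes were read in each subcluster and in other clusters. Ratios that a deletion in NK cells brings about would be looked for in NK cells, whereas T cells of the same library offer a comparison. Counting in each subset the genes that reached 20 CPM there, the higher genes kept their direction in 50 of 50 cases in subcluster 0, 54 of 54 in subcluster 2, 55 of 55 in subcluster 3 and 46 of 49 in subcluster 4, with medians of 1.53, 1.71, 1.77 and 1.61. The lower genes did so in 28 of 28, 24 of 24, 31 of 31 and 19 of 22. The genes had been chosen from the sum over these same cells, which by itself favours one direction. Sizes varied more: of the 106 genes that the naming rule gives, 36 had a ratio in at least 1 subcluster that was over 1.5-fold away from the ratio over all NK-like cells, 12 took the other sign in a subcluster, and 14 moved over 1.5-fold under an alternative. Cluster 6, which expresses Tmem176a and Tmem176b and stayed unnamed, had a median of 1.43 for the higher genes (38 of 40) and -0.93 for the lower genes (21 of 24). Medians of the higher genes were 0.18 in T-like cluster 3 (21 of 33) and 0.43 in T-like cluster 7 (31 of 32).

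Zc3h12a had a ratio of 2.63 in cluster 6, 0.23 (-0.63 to 1.05) in cluster 3 and 1.25 (0.89 to 1.62) in cluster 7. Pou2f2 had 3.46, 3.24, 3.66 and 3.56 in subclusters 0, 2, 3 and 4, 3.39 in cluster 6, -0.41 (-0.95 to 0.10) in cluster 3 and 1.96 (1.61 to 2.32) in cluster 7. Ifng had 1.27, 0.66, 0.82 and 2.06 in the subclusters, so its ratio was greatest in subcluster 4, and 0.08 (-0.15 to 0.31) in cluster 7. Ccr2 had -1.22, -2.37, -1.47 and -1.55 in the subclusters, -2.03 in cluster 6 and -0.49 in cluster 7. The ratios of these 4 genes in cluster 7 were thus nearer to 0 than in NK-like cells as a whole, and RNA of NK cells in the same droplets was not excluded there.

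**Figure D3:**
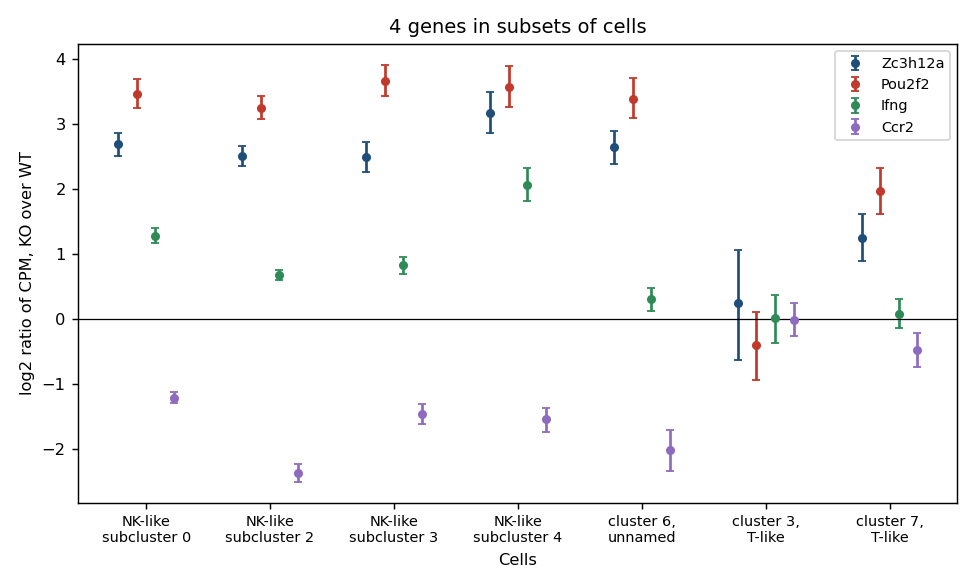
Log2 ratios of Zc3h12a, Pou2f2, Ifng and Ccr2 within NK-like subclusters and other clusters, with counting intervals. Pou2f2 had 3.66 in subcluster 3 and -0.41 in T-like cluster 3.

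To determine in how many cells these genes were read, each cell was thinned to 2000 UMIs, which left 8128 and 5033 NK-like cells. Zc3h12a and Pou2f2 are regulators read at low depth, whereas Gzmb, Ccl3 and Ccl4 are effector genes that many NK cells express. Zc3h12a had a UMI in 6.42% (5.90 to 6.98) of the cells in the library labelled WT and 33.0% (31.7 to 34.3) in the library labelled KO. Pou2f2 had 4.08% (3.66 to 4.54) and 37.0% (35.7 to 38.4), and Ifng had 23.4% (22.5 to 24.3) and 36.8% (35.5 to 38.2). Without thinning, Zc3h12a was read in 11.1% and 56.6% of the cells, Pou2f2 in 7.30% and 58.0%, and Ifng in 34.5% and 56.2%. All shares from here to the end of the paragraph are again after thinning to 2000 UMIs, unless stated. Icos had 3.26% and 9.36%, Xcl1 28.6% and 18.1%, Gzmb 49.0% and 55.1%, Ccl3 41.9% and 50.3%, and Ccl4 41.1% and 43.2%. Cd69 had 20.1% and 18.4%, but 30.6% and 32.6% without thinning. In T-like cluster 7, Zc3h12a had 3.74% and 7.71%, Pou2f2 4.38% and 8.42%, Icos 5.12% and 6.29%, and Ifng 10.4% and 10.9%, while Xcl1 (37.2% and 33.8%) and Cd69 (40.7% and 37.2%) were read in more cells than among NK-like cells. Pou2f2 had 12.2% and 8.15% in T-like cluster 3 and 18.9% and 18.6% in dendritic-like cells. Tnfrsf4 (0.332% and 0.159%), Tfrc (0.566% and 0.755%) and Il2ra (0.0738% and 0.0795%) were read in about as few or fewer cells than in T-like cluster 7, and so was Pou2af1 (0%, 0 to 0.0454, and 0.159%).

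To determine whether surface proteins differed, the 6 antibody tags were compared on NK-like cells as centred log2 ratios per cell. NK1.1, CD49B and NKP46 are used to mark NK cells, CD27 marks immature stages and CD11B mature ones, and IGG2A is an isotype control. CD11B had the largest difference, with means of -0.39 (SD over cells 1.19) in the library labelled WT and 0.76 (SD 1.66) in the library labelled KO, a difference of 1.14. NK1.1 had 0.20 (SD 0.53) and 0.90 (SD 0.65), a difference of 0.70, and CD27 had -1.39 (SD 1.13) and -1.16 (SD 1.53), a difference of 0.23. CD49B had 2.59 (SD 0.49) and 1.58 (SD 0.49), a difference of -1.01, and NKP46 had -0.41 (SD 1.01) and -0.65 (SD 0.78), a difference of -0.24. The isotype control IGG2A also differed, with -0.60 (SD 0.72) and -1.42 (SD 0.59), a difference of -0.82.

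In UMIs, NK1.1 had a mean of 65.5 (65.3 to 65.7) and 148.2 (147.8 to 148.5) per NK-like cell, CD11B 55.0 and 197, CD27 28.3 and 58.1, CD49B 359 and 261, NKP46 129 and 78.7, and IGG2A 80.9 and 35.8. Median UMIs were 19 and 23 for CD27, 29 and 36 for NKP46, the other direction than the mean, and 28 and 22 for IGG2A. CD49B and NKP46 set NK-like cells little apart in the library labelled WT. Median CD49B UMIs there were 243 on NK-like cells and 224 on T-like cluster 7, and the median NKP46 of 29 stood beside the isotype control at 28. In the library labelled KO median CD49B UMIs were 169 and 133. The median NKP46 there was 36 on NK-like cells and 27 on cluster 7, beside the isotype control at 22 on NK-like cells. T cells showed like differences for several tags: in T-like cluster 7 CD49B differed by -1.14, IGG2A by -0.76 and CD27 by 1.41 as centred log2 ratios. On that scale NK1.1 differed by 0.28 and CD11B by 0.25. Mean UMIs in cluster 7 differed more, at 11.5 and 26.6 for CD11B and 32.7 and 54.6 for NK1.1. In T-like cluster 3 NK1.1 differed by 0.36 and CD11B by 0.86, and in dendritic-like cells CD11B differed by 1.45. Tag levels thus differed between the libraries in cells other than NK cells too, and the sign of CD27, CD49B and NKP46 on NK-like cells was not the same under each scale. The transcripts, named outside the fixed rule, had log2 ratios of 0.27 for Itgam (CD11B), -0.27 for Klrb1c (NK1.1), -0.70 for Cd27 and -0.77 for Ncr1 (NKP46).

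**Figure D4:**
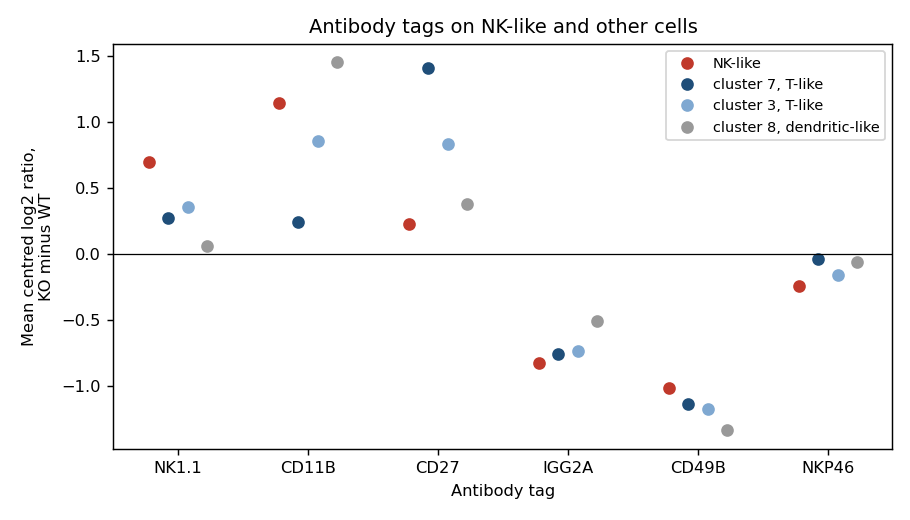
Difference between the libraries in the centred log2 ratio of each antibody tag, in NK-like cells and in clusters 7, 3 and 8. CD11B differed by 1.14 in NK-like cells, 0.25 in T-like cluster 7 and 0.86 in T-like cluster 3, and CD49B by -1.01 in NK-like cells and -1.14 in cluster 7.

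To determine whether the makeup of the NK-like cells differed, they were subclustered without the 940 genes that differed 1.5-fold or more. The genes left out included the stage genes Cxcr3, Il7r, Thy1, Klrg1 and Cx3cr1. A difference in makeup would itself move such genes, so the shares below may understate it. NK cells pass from an immature stage with Tcf7, Emb and Ltb to a mature stage with Gzma and Prf1. The genes that describe the subclusters were chosen after their values were seen. Subcluster 2 had the mature pattern, with Gzma at 20177 CPM, Prf1 at 1220.4 CPM and Tcf7 at 10.8 CPM. Subcluster 4 had Tcf7 at 229 CPM, Emb at 288 CPM, Ltb at 911 CPM and Prf1 at 166 CPM, but its leading genes also included Cd74, H2-Aa and H2-Eb1 of antigen-presenting cells, Iglc3 of B cells and Cd3d and Tcrg-C4 of T cells, so it was given no stage. Subcluster 2 held 50.4% (49.3 to 51.4) of the NK-like cells in the library labelled WT and 55.0% (53.6 to 56.3) in the library labelled KO. Subcluster 4 held 8.27% (7.69 to 8.86) and 13.1% (12.2 to 14.1). Subcluster 0, with Tcf7 at 81.8 CPM and Thy1 at 266 CPM, held 27.4% (26.4 to 28.3) and 22.9% (21.8 to 24.1), and subcluster 3 held 13.5% (12.8 to 14.2) and 8.19% (7.46 to 8.96). Subcluster 1, with Xcl1 at 3866 CPM, held 0.495% and 0.757%. In total 9.74% of the cells would need to move to even out the shares, but this distance was 42.3% at resolution 1.0 and 86.7% with all variable genes.

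To determine which other cells were present, all kept cells were assigned to classes by marker genes. The cells had been sorted as NK cells, so the other classes reflect the sort as well as the spleen. NK-like cells made up 73.5% (72.7 to 74.3) of the library labelled WT and 66.3% (65.3 to 67.4) of the library labelled KO. T-like cells, which express Cd3e and Cd3g, made up 12.5% (11.9 to 13.1) and 23.9% (22.9 to 24.8). Much of this difference came from cluster 14, with 4 cells in the library labelled WT (0.0339%) and 846 in the library labelled KO (10.6%, 9.95 to 11.3), while cluster 7 held 8.02% and 10.7% and cluster 3, with Cd8a and Cd8b1, 4.39% and 2.56%. Dendritic-like cells, which express Cd74 and H2-Aa, made up 1.36% and 1.104%, platelet-like cells with Pf4 0.169% and 0.276%, and basophil-like cells with Cd200r3 0.102% and 0.0627%.

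No cluster was B-like, although Cd79b and Tnfrsf13b were higher in NK-like cells of the library labelled KO. Unnamed clusters made up 12.4% and 8.34%: cluster 6 held 7.32% and 4.48%, cluster 4, with Cxcr6 and Il4, 4.14% and 1.71%, cluster 9, led by the interferon-stimulated genes Cxcl10 and Ifit1, 0.550% and 0.376%, and cluster 10, led by the cycling genes Birc5 and Mki67, 0.381% and 1.78%. NK-like cells of the 2 libraries fell largely into different clusters. Clusters 0, 1 and 5 held 3351, 4517 and 650 cells of the library labelled WT against 173, 351 and 28 of the library labelled KO, whereas clusters 2, 13 and 15 held 146, 22 and 1 against 3548, 625 and 562.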

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

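No paired analysis was possible, and the 2 alternatives that fit the L numbers as runs or as blocks were not run, because the cells of each genotype were pooled in 1 matrix and could not be mapped to L numbers. Leaving out cells above 2 times the median UMIs, including clusters 6, 9 and 10, taking NK-like cells from resolution 1.0, leaving out genes carried by 1 cell, leaving Il6 out of its list, subtracting the tags of cluster 7 or 3 and lowering the minimum to 40 cells were chosen after seeing the data.

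The number of 2-fold genes stayed between 81 and 109 under 13 alternatives. The genes themselves changed more: of the 94, 60 were among the 81 over all kept cells, and 83 to 94 were kept under the others. The number followed the minimum and the fold by construction: 224 genes (135 higher, 89 lower) at 5 CPM, 1462 (798 and 664) with no minimum beyond 4 counts, 42 (32 and 10) at 50 CPM and 292 (135 and 157) at 1.5-fold. Zc3h12a ranged from 2.43 to 2.73 over the alternatives, Pou2f2 from 2.90 to 3.51, Ifng from 0.75 to 1.01 and Ccr2 from -1.86 to -1.55. Of the values of named genes, 956 stayed within their counting interval, 316 moved and 0 of the genes at 2-fold or more took the other sign.

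Of the list medians, 216 stayed within the tolerance, 100 moved and 7 reversed, where reversed means that a list outside the central 95% of random lists took the other sign, and the cause was not tested. Medians inside that range were counted as moved or not, and 8 of these lists took either sign as well, from -0.28 to 1.41 for cell cycle genes and -0.18 to, as a mean, 0.08 for trafficking genes. Costimulatory and TNF receptor family genes reversed to 0.29 over all kept cells, 0.0057 without mitochondrial, ribosomal-protein and immunoglobulin genes in the total, 0.29 with members from 1 CPM and 0.43 as a mean. Residency and ILC1 genes reversed to -0.036 without cells above 2 times the median UMIs, -0.044 with clusters 6, 9 and 10 and -0.25 with members from 1 CPM. Between 10 and 15 lists lay outside the central 95% of random lists, against 12.

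As shares of the summed tags, log2 ratios were 1.06 for NK1.1, 1.72 for CD11B, 0.92 for CD27, -1.29 for IGG2A, -0.58 for CD49B and -0.83 for NKP46. From median UMIs they were 1.23 for NK1.1, 1.87 for CD11B, 0.28 for CD27, -0.35 for IGG2A, -0.52 for CD49B and, reversed, 0.31 for NKP46. With cluster 7 subtracted they were 0.42 for NK1.1, 0.90 for CD11B, -0.062 for IGG2A and, reversed, -1.18 for CD27 and 0.12 for CD49B. With cluster 3 subtracted they were 0.34 for NK1.1, 0.28 for CD11B, -0.092 for IGG2A, -0.085 for NKP46 and, reversed, -0.61 for CD27 and 0.16 for CD49B. The cause was not tested. CD11B and NK1.1 were higher in the library labelled KO on all of these scales.

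The distance between the subcluster shares was 42.3% at resolution 1.0 and 86.7% with all variable genes, where the differing genes themselves part the cells. Platelet-like cells were 0.0176% and 0.0131% under the stricter filter, since they hold few genes. At resolution 1.0, T-like cells were 11.6% and 22.9% and unnamed cells 13.3% and 9.35%. Without cells above 2 times the median UMIs, NK-like cells were 75.6% and 67.5%, T-like cells in the library labelled KO 25.0%, dendritic-like cells 0.429% and 0.433% and unnamed cells 11.5% and 6.70%, since dendritic-like and cycling cells are deep. Of the shares of cells with a UMI, 45 moved with the thinning depth and 7 did not. Depth limited genes such as Pou2af1, read from 3 and 13 counts.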

Other observations

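Cluster 14, with 846 cells in the library labelled KO, combined T cell and NK cell genes, of which those named here were chosen after their values were seen. Cd3e, a chain of the T cell receptor complex, had 1435 CPM there against 10.7 CPM in NK-like cells of the same library, and Trac had 218 CPM. The NK adaptor genes Tyrobp and Fcer1g had 1797 and 2947 CPM, Ncr1 had 283 CPM, and the granzyme genes Gzma and Gzmb had 11761 and 1195 CPM. Cd8a had 125 CPM beside 6.03 CPM for Cd8b1. Cd4 had 0 counts, but it was also at 0 CPM in NK-like cells of both libraries and in cluster 7 of the library labelled KO. Itga1 had 118 CPM, Cxcr6 236 CPM, Ikzf2 244 CPM and Klra5 134 CPM, whereas Eomes had 21.8 CPM. Zc3h12a (167 CPM), Pou2f2 (243 CPM) and Irak3 (110 CPM) lay well above NK-like cells of the library labelled WT.

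T cell receptor segments differed between the libraries in cluster 3. In the library labelled WT, 260 of 279 cells with Trav4-3 also had Trbv13-2, whereas in the library labelled KO 51 of 53 cells with Trav7-5 also had Trbv15, and 0 of 4 with Trav4-3 had Trbv13-2. In cluster 14, Trdv1 was read in 296 cells and Trbv16 in 213, with both in 10. The constant segment Trdc had 29.0 CPM there, beside 35.9 CPM in NK-like cells and 88.9 CPM in cluster 7 of the same library. Of 2-fold genes, S100a8 and S100a9 drew 100% and 99.8% of their counts in the library labelled KO from 1 cell.

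Of the tests in this part, the share of the library labelled WT among the cells that match cluster 14 was set out before its result was seen, and all others were chosen after the results were seen.

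Zc3h12a was higher in NK-like cells of the library labelled KO, though the label names a deletion. Swapped labels are argued against by the published Regnase-1 targets, whose median stood at the 100th percentile of random lists (99.9th without Il6) in the direction that the labels give. A difference between the libraries that acts alike on every cell type is argued against by T-like cluster 3, where Zc3h12a had a log2 ratio of 0.23 (-0.63 to 1.05) against 2.63. T-like cluster 7 had 1.25 (0.89 to 1.62), and the T cell receptor segments of cluster 3 differ between the libraries, so a difference in part of the cell types stays open. The genotype itself stays open and was not tested: transcripts that lack exons may still be read at the 5' end, and loss of Regnase-1 may spare its own transcript.

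Pou2f2 was higher in T-like cluster 7 of the library labelled KO, at 1.96. A difference acting on every cell type is argued against by cluster 3, at -0.41 (-0.95 to 0.10). RNA of NK cells in the same droplets may contribute, and 3 sets of NK genes were tried in turn to set aside cells with such RNA: 10 genes chosen in exploration, then the 13 fixed markers, then 4 receptor genes, taken because the 13 markers left too few cells. Cells low in the 10 genes gave -0.13 (-1.28 to 0.98; 100 and 79 cells), those low in the 13 markers 4.08 (0.74 to 9.70; 7 and 2 cells), and those without the 4 receptor genes 0.91 (0.29 to 1.54; 390 and 328 cells). The first and last of these intervals lie under 1.96, as RNA of NK cells would need. T cells that themselves express NK genes and carry the difference would give the same split, so the split cannot tell these apart. The sets of 10 and 4 genes were also picked after the pattern was seen, and the 13 fixed markers left too few cells. The question stays open.

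Cluster 14 held cells of the library labelled KO almost alone. Doublets of NK and T cells are argued against by its median of 2834 UMIs, under the 4103 of NK-like cells. A single clone behind the whole cluster is argued against by Trbv16, read in 30.3% (26.9 to 33.8) of the cells with a Trbv gene, though Trdv1 was read in 86.8% (82.7 to 90.2) of the 341 cells with a Trdv gene, so expanded clones in part of it stay open. When the 940 differing genes were left out, the share of NK-like cells placed differently went from 87.6% to 9.27%, but the cluster with 797 of the 846 cells still held 0.271% (0.185 to 0.382) of the library labelled WT and 10.9% of the library labelled KO, which argues against counterparts set apart by these genes as the whole cause. Of its cells 32 (3.54%, 2.43 to 4.96) came from the library labelled WT, 18 of them platelet-like, under the 10% that such counterparts would need and not under the 2% set against any, so a few counterparts stay open, as do the sort and the genotype.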
